A study of Mus musculus with 88 samples.

How the data were processed

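Gene expression was measured in tibialis anterior muscle of mice by poly(A)-enriched RNA sequencing, in 88 libraries that fall into 12 groups. The C26 experiment holds 60 libraries of Balb/c mice in 8 groups, by sex and by PBS, 10, 20 or 25 days after tumour cell injection. The APC experiment holds 28 libraries in 4 groups, by sex and by genotype, wild type or APC+/Min. Every library was placed in its group by its title, which also gives the replicate number. The design text gives 6 to 8 mice in a group, and each library was taken as 1 mouse. The labels do not say this library by library, so p-values measure the spread between the libraries as the labels group them.

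The deposited values are estimated counts per gene, which need not be whole numbers (9.70% of the values are not). The submitters' processing notes name Salmon 1.10.2, R 4.4.1, edgeR, limma and the builds GRCm39 and mm39, without saying which step each was used for. The annotation, the trimming and the strand setting behind the estimated counts are not given in the sources used here. The table holds 56065 gene identifiers, and no identifier stood for something other than a gene. Symbols were taken from the GENCODE M21 annotation, which belongs to another genome build, so it was used for names and gene lengths alone and no coordinates are given. It named 51272 of the identifiers, which hold 99.0% of the counts. Library totals ran from 18.2 to 30.7 M counts (M, mega) with a median of 21.5 M. The counts set the precision of low genes. Where a group held no count of a gene, a fold is a lower bound computed against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with an exact interval for counting error only. Transcripts of near-identical copies (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Saa1 and Saa2, Amd1 and Amd2, Hspa1a and Hspa1b, and ribosomal protein genes with their pseudogenes) share reads that the counting could split, so values of single members are uncertain. The same holds for antisense genes, since the strand setting is unknown.

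Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr by group with a minimum count of 10 and a minimum total of 15, glmQLFit with robust estimation and a trended dispersion, glmQLFTest). The experiments differ in strain and were normalized and fitted apart, each in 1 model with a mean for each group and no covariate. The filter left 15742 genes in the C26 experiment and 14795 in the APC experiment, with a median of 5.11 and 7.09 prior degrees of freedom. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and a gene was called at an adjusted p below 0.05. Log2 fold changes are given with their standard errors (SE). A value given after a gene name without a unit is its log2 change, followed by the SE after ±. Levels are TMM-normalized CPM, given as the mean and standard deviation (SD) of a group, except library measures (Alb, Xist, Ddx3y and the mitochondrial share), which are relative to the library total. A difference between the sexes in the response was tested as an interaction, the change in males minus the change in females. All comparisons of tumour groups with PBS within a sex share the same controls, so overlaps between times were set beside 20 simulations of unchanged groups against those controls and 10 random splits of the controls, some of which were drawn more than once. Overlaps of calls were tested with a one-sided Fisher exact test per direction among genes tested in both comparisons. That test treats genes as independent, which they are not, so its p-values can be far too small.

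Fixed lists of genes, 42 in all, were tested with limma 3.58.1: ubiquitin ligases of muscle atrophy, proteasome, autophagy and lysosome, glucocorticoid and FoxO responsive genes, IL-6, STAT3 and acute phase, NF-kB and cytokines, interferon response, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, mitochondrial biogenesis, tricarboxylic acid cycle, fatty acid oxidation, glycolysis and glycogen, fast fibre, slow fibre, excitation-contraction coupling, sarcomere, denervation, myogenic genes, extracellular matrix, cytosolic ribosomal proteins, integrated stress, heat shock, oxidative stress, polyamine metabolism, p53 targets, DNA methylation, histone modification, circadian clock, immediate early genes, cell cycle, markers of macrophages, neutrophils, T and B lymphocytes, endothelium, fibro-adipogenic progenitors, adipocytes, Schwann cells, smooth muscle, erythroid cells and epithelium, and sex chromosome check genes. Each list was compared with the other genes by camera with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Members were also adjusted over the list alone.

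The groups, comparisons, tests, lists, named genes and most alternatives were chosen before the data were examined. Genes named for a comparison with PBS or wild type are the 6 with the highest and the 6 with the lowest fold change among called genes with a mean of at least 1 CPM and every treated library on the same side of the control median. Predicted genes, receptor segments and histone genes were left out of this rule. To these come up to 4 members of a described list with the lowest adjusted p, members that go against the list, and always Fbxo32 and Trim63. For other comparisons the 5 called genes with the lowest p in each direction were named, with called list members, and for overlaps the 10 shared genes with the largest product of fold changes. Some genes that meet these rules are not reported here.

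The alternatives were DESeq2 size factors, DESeq2 1.42.0 (Wald test), limma-voom, limma-voom with quality weights, no filter, a stricter filter of 1 CPM, a fit to only the groups compared, the replicate number as a block, fry, and an adjusted p below 0.01 for overlaps. Chosen after seeing the data were leaving out each library in turn, leaving out the 7 C26 libraries with Alb at 10 CPM or more, and a covariate for the length trend. The length trend of a library is the slope, on log2 gene length, of its log2 CPM after subtraction of each gene's mean. It was fitted over 11147 genes (C26) and 10383 genes (APC), without ribosomal protein, proteasome and oxidative phosphorylation genes and mitochondrial transcripts, and lengths were found for 99% and 99.1% of the genes above the level used. The test was checked first on simulated counts drawn from the means and dispersions of the real libraries, with 200 genes changed. Genes were drawn independently, without a trend shared across a library such as that of length, so recovery in the real libraries may differ. Figures were drawn with matplotlib 3.10.9 from tables made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. No library was left out of the main tests.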

Results

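Tibialis anterior muscle, a fast muscle of the lower leg, was profiled by mRNA sequencing in 2 mouse models of colorectal cancer and in both sexes, and the study's title names cachexia, the wasting that accompanies cancer. C26 is a colon carcinoma line transplanted into Balb/c mice, and muscle was taken 10, 20 or 25 days after injection, or 25 days after PBS. No PBS group was taken at 10 or 20 days. Differences from PBS at those days, and steps between days, therefore mix time with the tumour and the day of collection. APC+/Min mice carry a mutant allele of the tumour suppressor Apc, form intestinal tumours and were sampled at 20 weeks of age beside wild types. Female C26 groups held 7 (PBS), 8 (10 days), 8 (20 days) and 6 (25 days) libraries, and male groups 8, 8, 7 and 8. Among APC libraries, each sex had 8 wild type and 6 APC+/Min libraries. Totals ran from 18.2 to 23.6 M counts in C26 females and from 18.9 to 30.7 M counts in C26 males. In the APC experiment they ran from 18.4 to 25.8 M counts in females and from 19.4 to 28 M counts in males.

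Some libraries differed from their group in ways that the labels do not explain. Alb, the plasma protein albumin made in liver, reached 189 CPM in male 20 days replicate 3, 106 and 68.5 CPM in male 25 days replicates 4 and 5, and 10 CPM or more in 4 other C26 libraries. Male 25 days replicate 2 held Xist, the RNA of the inactive X chromosome, at 191 CPM beside Ddx3y, a Y-linked gene, at 101 CPM, while the other C26 male libraries held Xist at 0.387 CPM or less. Female 25 days replicate 6 held short transcripts in excess (length slope -0.524) and little Xist (48.4 CPM). No library was removed for this.

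At 10 days after C26 injection, Fbxo32 and Trim63, which encode the muscle ubiquitin ligases atrogin and MuRF, lay near the PBS level in both sexes. In females Fbxo32 was at 126.8 ± 37.1 CPM (SD, n = 8) against 90.77 ± 29 CPM (SD, n = 7), a log2 change of 0.48 ± 0.34 (SE), and Trim63 differed by 0.05 ± 0.30. In males the log2 differences were -0.24 ± 0.32 for Fbxo32 and -0.02 ± 0.29 for Trim63. No gene passed in either sex by edgeR (500 genes in females and 363 in males at an unadjusted p under 0.05, DESeq2 5 and 2, limma-voom 0 and 0). Without the filter, 26 genes passed in males. Members of the lists did not pass over all genes either, although in females mitochondrially encoded transcripts lay above the other genes as a set (median log2 change 0.31, camera adjusted p = 1.3e-08, adjusted p = 0.20 with an estimated correlation) and heat shock genes below (median -0.26, 2.5e-07, adjusted p = 0.20 with an estimated correlation). In males extracellular matrix genes lay above the other genes (median 0.19, camera adjusted p = 4.1e-13, adjusted p = 0.98 with an estimated correlation). In simulated data, 65.7% of genes changed 2-fold were recovered in the female comparison and 61.2% in the male one. Those data hold no trend shared across a library, so recovery in the real libraries may be lower.

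After 20 days in females, acute phase genes and the metallothioneins Mt1 and Mt2 rose. Lcn2, an iron-sequestering protein of the innate response, rose 15.5-fold to 7.86 ± 6.54 CPM (SD, n = 8) from 0.496 ± 0.222 CPM (SD, n = 7), and Serpina3n, a protease inhibitor of the acute phase, rose 9.69-fold (log2 change 3.28 ± 0.49, SE). Mt1 and Mt2 rose by 2.93 ± 0.56 and 2.72 ± 0.64 log2 units, Odf3l2 by 2.96 ± 0.56 and the acyl-CoA thioesterase Acot1 by 2.51 ± 0.51. Fbxo32 rose 3.36-fold (305 ± 208 against 90.8 ± 29 CPM, adjusted p = 0.0028) and Trim63 2.38-fold (adjusted p = 0.02). The stretch-responsive genes Ankrd2 and Csrp3 were lower, at -2.92 ± 0.57 and -2.60 ± 0.53, the M-band protein Myom3 at -2.21 ± 0.50 and Shc4 at -2.12 ± 0.35. The PBS levels of Ankrd2 and Csrp3 varied widely between libraries. Ankrd2 was at 343 ± 306 CPM (SD) after PBS against 45.3 ± 15.5 CPM at 20 days, and Csrp3 at 664 ± 552 against 110 ± 48.7 CPM. Spsb4 was at -1.82 ± 0.45, and Akap5 also fell.

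Glucocorticoid and FoxO responsive genes rose in females at 20 days, with 9 of 24 passing over all genes (17 adjusted over the list alone, camera adjusted p = 2.1e-17), among them Glul, the glutamine synthetase, at 0.93 ± 0.17, Fkbp5, a glucocorticoid receptor co-chaperone, at 1.38 ± 0.30 and Gadd45a at 1.24 ± 0.27. Of the IL-6, STAT3 and acute phase genes 10 of 24 rose (13 adjusted over the list alone, 3.7e-14), with Osmr, the oncostatin M receptor, at 1.06 ± 0.16 and Lbp at 1.56 ± 0.33. Neutrophil markers rose in 4 of 8 cases (8 adjusted over the list alone, 1.4e-11), including S100a9 at 3.14 ± 0.58 and S100a8 at 3.01 ± 0.61. These 3 lists held with an estimated correlation (adjusted p = 0.011, 0.014 and 0.014). Erythroid markers rose in 3 of 9 (8 adjusted over the list alone, 4.6e-10, adjusted p = 0.10 with an estimated correlation). Slc4a1 was at 2.34 ± 0.50. Slow fibre genes fell in 3 of 15 (5 adjusted over the list alone, 1.1e-05, adjusted p = 0.26 with an estimated correlation). Lmcd1 was at -1.40 ± 0.26 and Casq2 at -0.68 ± 0.19. Sarcomere genes fell in 5 of 28, with Cryab at -0.94 ± 0.25 and Ldb3 at -0.46 ± 0.13, while Tmod4 rose by 0.39 ± 0.11 (10 fell and 1 rose adjusted over the list alone, 0.0023, adjusted p = 0.47 with an estimated correlation). No member of the slow fibre or sarcomere lists passed in the step from 10 to 20 days in females. The falls in both lists at 20 days therefore rest on the comparison with the PBS libraries. In the ubiquitin ligase list 3 of 20 rose (4 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.43), with Asb2 at 0.39 ± 0.10 beside Fbxo32 and Trim63. By edgeR 261 of 15742 genes passed, 176 higher and 85 lower, and 102 of them by 2-fold or more. The count was 405 by DESeq2, 474 with the length slope, 151 without the filter and 134 with the other groups left out. It was 121 without female PBS replicate 7, 162 without female PBS replicate 6, and 144, 162 and 153 without female 20 days replicates 1, 6 and 7.

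Neutrophil and acute phase genes rose in females at 25 days. Retnlg, a resistin-like peptide of neutrophils, was 41.2-fold higher (9 counts in all PBS libraries), Serpina3n rose 21.9-fold to 33 ± 18.3 CPM (SD, n = 6), S100a9 17.0-fold, and Lcn2, Mt2 and Mt1 by 4.78 ± 0.83, 3.81 ± 0.69 and 3.77 ± 0.60 log2 units (SE). Fbxo32 rose 2.86-fold (260 ± 66 CPM, adjusted p = 0.0075) and Trim63 2.29-fold (263 ± 142 CPM, adjusted p = 0.024). The cardiac actin gene Actc1 was lower, at -2.28 ± 0.50, Papln at -2.22 ± 0.51, Shc4 at -1.95 ± 0.38, Akap5 at -1.92 ± 0.56, Spsb4 at -1.72 ± 0.49 and the transcription factor Foxo6 at -1.54 ± 0.32. All 8 neutrophil markers rose (8 adjusted over the list alone, camera adjusted p = 8.1e-16), with Cxcr2, a chemokine receptor, at 3.13 ± 0.53, and 6 of 8 rose without replicate 6. IL-6, STAT3 and acute phase genes rose in 14 of 24 (16 adjusted over the list alone, 1.4e-22), with Osmr at 1.57 ± 0.17 and Stat3 at 1.08 ± 0.18. Glucocorticoid and FoxO genes rose in 10 of 24 (19 adjusted over the list alone, 1.8e-15), with Fkbp5 at 1.92 ± 0.31. With an estimated correlation these 3 lists held (adjusted p = 0.0021, 0.0019 and 0.0086).

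Macrophage markers rose in 4 of 18 in the same females (6 adjusted over the list alone, 3.8e-06, adjusted p = 0.50 with an estimated correlation), the complement genes C1qb at 1.78 ± 0.42, C1qa at 1.60 ± 0.44 and C1qc at 1.49 ± 0.43 and the scavenger receptor Cd163 at 1.27 ± 0.33. Replicate 6, the library with excess short transcripts, held the highest macrophage signal (mean log2 CPM 5.3, next 3.47), and without it 1 of 18 markers passed (list median 0.43). Endothelial markers rose in 5 of 17, among them Vwf at 0.73 ± 0.16 and Ly6c1 at 0.99, against Kdr, a receptor for VEGF, at -1.04 ± 0.25 (7 rose and 1 fell adjusted over the list alone, 0.0022, adjusted p = 0.50 with an estimated correlation). Of 12 adipocyte markers 2 rose, the lipase gene Lipe (0.88 ± 0.14) and Plin4 at 0.92 (2 adjusted over the list alone, 0.0088, adjusted p = 0.43 with an estimated correlation). Of 20 ubiquitin ligase genes 3 rose and Fbxo40 fell, at -0.54 ± 0.14 (3 and 1 adjusted over the list alone, camera adjusted p = 0.55). Without replicate 6, 3 ubiquitin ligase genes rose and 0 fell, and the adipocyte markers had a median log2 change of 0.05 against 0.52 with it. In this comparison 576 genes passed, 417 higher and 159 lower, and 232 by 2-fold or more. The count was 1555 with quality weights, 925 with the length slope and 376 without the filter.

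Males at 20 days had increases in acute phase genes, among them 9 made mainly in liver. The 9 were Saa1, Saa2, Fga, Fgb, Fgg, Hp, Orm1, Itih3 and Itih4. Orm1, Itih3 and Itih4 are not in the fixed list and were among the genes named for high fold changes in C26 males. Without the libraries rich in Alb 0 of these 9 passed, and their median log2 change went from 6.38 to 1.12, Itih3, Itih4 and Hp among those lost. Itih3 and Itih4, secreted inhibitors made mainly in liver, changed by 6.38 ± 1.11 and 5.41 ± 0.91 log2 units (SE), S100a9 and S100a8 by 3.53 ± 0.59 and 3.22 ± 0.63, Serpina3n by 3.51 ± 0.47 (20.8 ± 20 CPM, SD, n = 7, against 1.81 ± 0.554, n = 8) and the complement gene C4b by 2.77 ± 0.41. Papln lay lower, at -1.99 ± 0.46, Foxo6 at -1.46 ± 0.30, the potassium channel gene Kcnh2 at -1.12 ± 0.28, Pthlh at -1.12 ± 0.27, the collagen gene Col4a4 at -0.98 ± 0.21 and Lingo3 at -0.81 ± 0.21. Fbxo32 and Trim63 did not pass, at 0.59 ± 0.33 (adjusted p = 0.55) and 0.53 ± 0.30 (0.56). IL-6, STAT3 and acute phase genes rose in 12 of 24 (21 rose and 1 fell adjusted over the list alone, camera adjusted p = 4.7e-20), with Osmr at 1.28 ± 0.16, Lbp at 1.95 ± 0.32 and haptoglobin, Hp, at 4.63 ± 0.87. Of the neutrophil markers 5 of 8 rose (8 adjusted over the list alone, 2.3e-14), with Cxcr2 at 2.57 ± 0.52. Glucocorticoid and FoxO genes rose in 3 of 24 (16 adjusted over the list alone, 9.1e-13), Mt1 at 2.40 ± 0.53, Mt2 at 2.53 ± 0.61 and Fkbp5 at 1.15 ± 0.29. With an estimated correlation these 3 lists held (adjusted p = 0.0041, 0.0041 and 0.024). Ly6c1, Aqp1 and Esam rose among 17 endothelial markers (10 rose and 1 fell adjusted over the list alone, 8.8e-07, adjusted p = 0.20 with an estimated correlation). Ly6c1 was at 0.96 ± 0.20. By edgeR 155 genes passed, 140 higher and 15 lower, against 199 higher and 128 lower with quality weights and 78 and 45 with the other groups left out. The count was 42 without the libraries rich in Alb, where 4 of 24 IL-6, STAT3 and acute phase genes rose, 71 without male 20 days replicate 3, and 70 by limma-voom.

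At 25 days in males the change was broad, with 3518 genes passing, 1826 higher and 1692 lower, and 829 by 2-fold or more. Lcn2 rose by 5.70 ± 0.72 log2 units (SE; 80 ± 89.5 CPM, SD, n = 8, against 1.55 ± 0.946, n = 8), the acute phase genes Saa2 by 8.66 ± 1.73 and Orm1 by 6.01 ± 1.23, Retnlg by 6.36 ± 0.86 and Mt2 by 5.29 ± 0.68. PBS libraries held only 5 counts of Saa2 and 5 of Retnlg. Without the libraries rich in Alb the median log2 change of the same 9 liver-type acute phase genes went from 6.01 to 2.90 and 6 passed. Itih3, with 10 counts after PBS, had a ratio of 71.3 (38.5 to 149, counting error only). Among the named genes that fell, Cilp2 was at -3.24 ± 0.68, Papln at -3.20 ± 0.48, the keratan sulfate proteoglycan Kera at -3.04 ± 0.62, Chad at -2.79 ± 0.71 and tenomodulin, Tnmd, at -2.49 ± 0.49, beside Pakap at -3.01 ± 0.95. Fbxo32 rose 2.53-fold (409 ± 320 against 162 ± 41.8 CPM, adjusted p = 0.0021) and Trim63 2.58-fold (350 ± 281 against 136 ± 22 CPM, adjusted p = 0.00061).

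**Figure D1:**
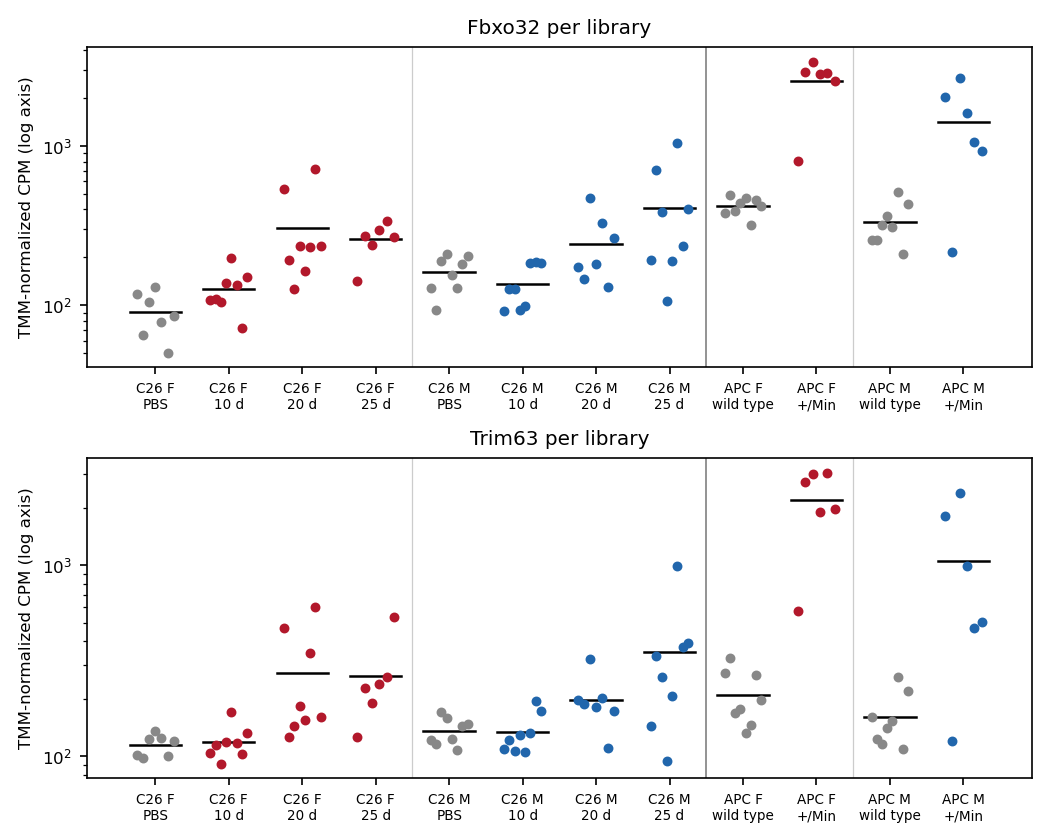
TMM-normalized CPM (log axis) of Fbxo32 and Trim63 in each library by group, with points for libraries, bars for group means, gray for controls, red for female and blue for male tumour groups. In APC+/Min females Fbxo32 averaged 2565 CPM against 422 CPM in wild types, and in C26 females it averaged 305 CPM at 20 days against 90.8 CPM after PBS.

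Of the IL-6, STAT3 and acute phase genes 21 of 24 rose in males at 25 days (22 adjusted over the list alone, camera adjusted p = 5.2e-18), among them Osmr at 1.80 ± 0.15, Serpina3n at 4.90 ± 0.48, Lbp at 2.92 ± 0.32 and Bcl3 at 2.73 ± 0.31, while Lifr, the receptor of leukemia inhibitory factor, lay lower, at -0.50 ± 0.13. All 8 neutrophil markers rose (8 adjusted over the list alone, 7e-13), S100a9 by 5.19 ± 0.60 and Cxcr2 by 4.36 ± 0.52. These were the lists that held with an estimated correlation (adjusted p = 0.0081 and 0.0081). Glucocorticoid and FoxO genes rose in 16 of 24 (17 adjusted over the list alone, 8.5e-11, adjusted p = 0.056 with an estimated correlation). Mt1 was at 5.11 ± 0.59 and the translation repressor Eif4ebp1 at 2.12 ± 0.27. Proteasome genes rose in 24 of 33 (29 adjusted over the list alone, 1.9e-12, adjusted p = 0.28 with an estimated correlation). Psmd3 was at 0.41 ± 0.08 and Psma7 at 0.87 ± 0.18. Autophagy and lysosome genes rose in 12 of 29 and fell in 1 (14 and 2 adjusted over the list alone, 0.00042, adjusted p = 0.15 with an estimated correlation). Map1lc3b was at 0.96 ± 0.13, Lamp2 at 0.56 ± 0.09 and Bnip3 at 0.63 ± 0.10 against Atg16l1 at -0.20 ± 0.07. Ribosomal protein genes rose in 30 of 43 (40 adjusted over the list alone, 3.2e-10, adjusted p = 0.45 with an estimated correlation). Rpl10a was at 0.77 ± 0.20, and the length slope of the same libraries averaged -0.0195 ± 0.15 (SD) against 0.088 ± 0.0244 after PBS. With that slope as a covariate 19 of them passed. Heat shock genes rose in 11 of 18 (14 adjusted over the list alone, 3.4e-05, adjusted p = 0.15 with an estimated correlation). Dnajb4 was at 0.79 ± 0.17 and Hspb1 at 1.38 ± 0.30. Oxidative stress genes rose in 15 of 22 and fell in 2 (18 and 2 adjusted over the list alone, 5.4e-09, adjusted p = 0.078 with an estimated correlation). Gpx3 was at 2.07 ± 0.25, while Sod2, the mitochondrial superoxide dismutase, lay lower, at -0.41 ± 0.10 and Gsta4 at -0.39 ± 0.12.

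Members of calcium handling and energy lists fell in males at 25 days. In the excitation-contraction coupling list 12 of 21 fell (13 adjusted over the list alone, camera adjusted p = 2.1e-06, adjusted p = 0.15 with an estimated correlation). Sypl2 was at -0.84 ± 0.14. In the glycolysis and glycogen list 14 of 27 fell and 3 rose (15 and 4 adjusted over the list alone, 0.0027, adjusted p = 0.45 with an estimated correlation), with the pyruvate kinase gene Pkm at -0.72 ± 0.12 and Gpd1 at -0.74 ± 0.14 against Ppp1r3c at 1.40 ± 0.23, Fbp2 at 0.81 ± 0.16 and Hk1 at 0.39. Tricarboxylic acid cycle genes fell in 9 of 20 and rose in 1 (10 and 1 adjusted over the list alone, 0.00014, adjusted p = 0.45 with an estimated correlation). Pdhx was at -0.53 ± 0.10 against Idh2 at 0.67 ± 0.14. Mitochondrial biogenesis genes fell in 9 of 23 and rose in 1 (11 and 2 adjusted over the list alone, 0.0066, adjusted p = 0.51 with an estimated correlation). Esrra was at -0.57 ± 0.12, against Pprc1 at 0.44. Interferon response genes fell in 9 of 28, Ifit3 at -1.70 ± 0.31 and Gbp3 at -1.26 ± 0.27, while Irf9 rose by 0.70 ± 0.14 (9 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.05, adjusted p = 0.69 with an estimated correlation). Of the erythroid markers 8 of 9 rose (8 adjusted over the list alone, 0.002, adjusted p = 0.45 with an estimated correlation). Endothelial markers rose in 9 of 17 and fell in 2 (11 and 2 adjusted over the list alone, 0.00062, adjusted p = 0.45 with an estimated correlation). Ly6c1 was at 1.33 ± 0.20 against Kdr at -1.08 ± 0.22 and Cdh5 at -0.35 ± 0.11. Macrophage markers rose in 6 of 18 (6 adjusted over the list alone, 0.00023, adjusted p = 0.45 with an estimated correlation). Cd163 was at 1.51 ± 0.30. Immediate early genes rose in 9 of 20 (10 adjusted over the list alone, 3.4e-05, adjusted p = 0.39 with an estimated correlation). Junb was at 2.63 ± 0.33. Integrated stress genes rose in 7 of 25 and fell in 1 (8 and 1 adjusted over the list alone, 0.0064, adjusted p = 0.45 with an estimated correlation). Slc3a2 was at 1.07 ± 0.14, against Ddit3 at -0.51.

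Other lists held members that went both ways in males at 25 days. Among DNA methylation genes 3 rose and 5 fell of 19 (camera adjusted p = 0.69), with the demethylase Tet1 at -2.11 ± 0.39 and the methyltransferase Dnmt3a at -1.02 ± 0.22 against Gadd45a at 1.24 ± 0.26. Among histone modification genes 4 rose and 4 fell of 33 (0.37), with Kdm1a at 0.33 ± 0.07 and Hdac9 at -0.92. Circadian clock genes rose in 3 and fell in 5 of 19 (0.38), Bhlhe41 at -1.15 ± 0.19 and Dbp at -1.32 ± 0.24 against Nfil3 at 1.29 ± 0.23. The ubiquitin ligase list had 4 higher and 4 lower of 20 (0.40), its median at -0.10, its mean at 0.05 and its test pointing down, with Fbxo31 at 0.68 ± 0.16 and Cblb at 0.57 ± 0.15 against Fbxo40 at -0.43 ± 0.12 and Smurf1 at -0.46 ± 0.13. Extracellular matrix genes fell in 11 and rose in 4 of 34 (0.21), Col15a1 at -0.85 ± 0.14 against Mmp9 at 2.64 and Lox at 1.37. Polyamine genes rose in 3 and fell in 3 of 13 (0.23), the latter Amd1 (-1.17 ± 0.17), Amd2 and Smox (-0.83 ± 0.14). Denervation genes rose in 7 and fell in 2 of 22 (0.28), with Cdkn1a at 2.02 ± 0.34 and Myog at 1.54 ± 0.32. Targets of p53 rose in 7 and fell in 2 of 20 (0.056). NF-kB and cytokine genes rose in 4 of 20 and fell in 1 (0.014, adjusted p = 0.45 with an estimated correlation). Cxcl13 was at 4.77 ± 0.61 against Tnfaip3 at -1.42 ± 0.27. Fatty acid oxidation genes rose in 8 of 23 and fell in 1 (0.012, adjusted p = 0.59 with an estimated correlation). Cd36 was at 0.84 ± 0.12, against Hadh at -0.30 ± 0.09. Of 12 adipocyte markers 4 rose and 2, Plin1 and Car3, fell (0.047, adjusted p = 0.45 with an estimated correlation). Counts and camera adjusted p were 9 fell of 44 for nuclear-encoded oxidative phosphorylation (0.16), 0 of 13 for mitochondrially encoded transcripts (0.73), 2 fell of 18 for fast fibre (0.056) and 1 rose of 15 for slow fibre genes (0.76), the latter being Sln at 1.90 ± 0.37. They were 5 rose and 6 fell of 28 for sarcomere (0.29), 3 rose and 1 fell of 21 for myogenic genes (0.29), 1 fell of 24 for the cell cycle (0.90), 1 fell of 4 for T and B lymphocytes (0.21) and 4 rose and 4 fell of 18 for fibro-adipogenic progenitors (0.73). For Schwann cells 0 of 14 passed (0.97), for smooth muscle 1 rose and 1 fell of 13 (0.20), and for epithelium 0 of 6 (0.80). Of 5 sex chromosome check genes Xist passed (0.40), with its counts in replicate 2. Adjusted over the list alone, the counts of these lists were unaltered except for the ubiquitin ligases (4 rose, 6 fell), circadian clock (4 and 8), extracellular matrix (5 and 11), denervation (7 and 3), p53 targets (7 and 3), myogenic genes (3 and 0) and fibro-adipogenic progenitors (6 and 4).

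**Figure D2:**
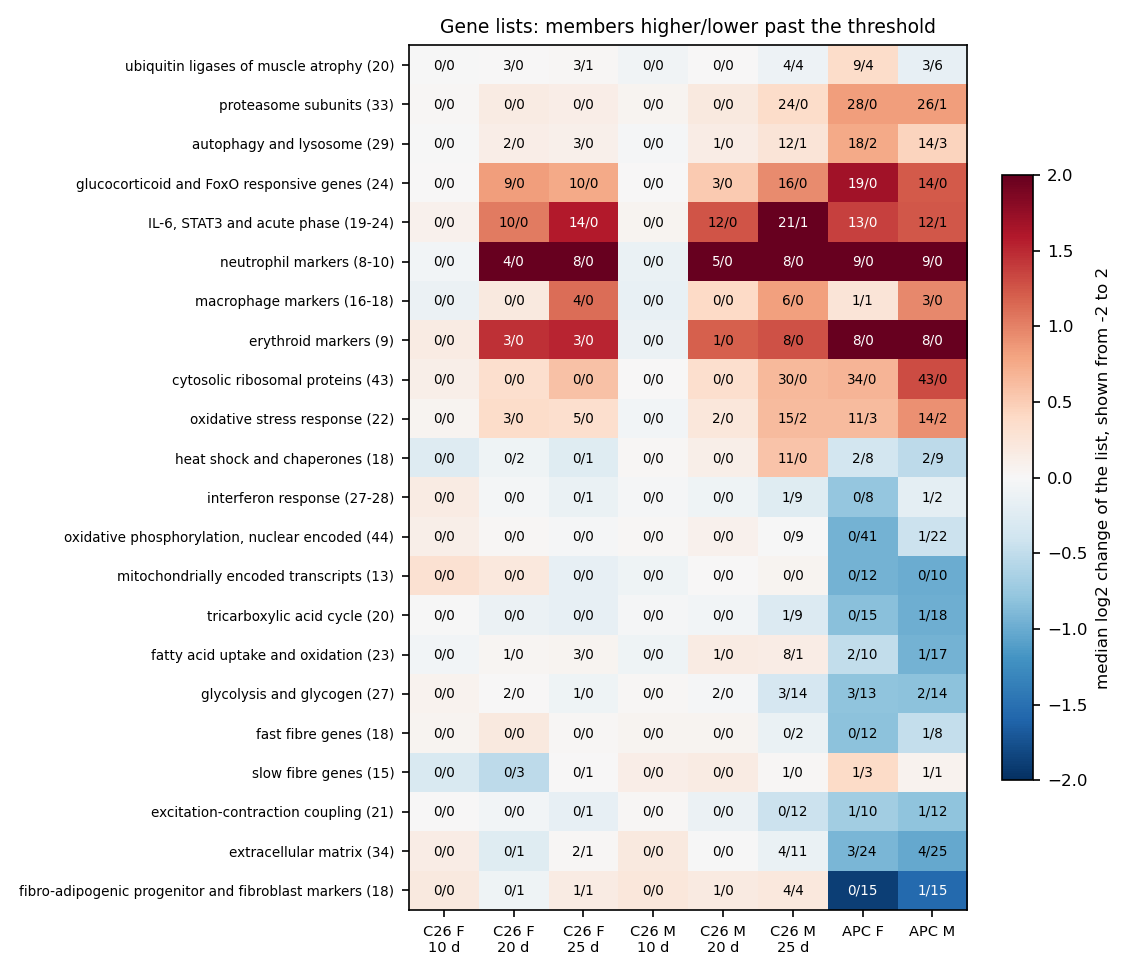
Median log2 change of 22 gene lists (colour, limited to -2 and 2) in 8 comparisons with PBS or wild type, with the numbers of members called higher and lower in each cell. In males at 25 days 24 of 33 proteasome genes and 21 of 24 IL-6, STAT3 and acute phase genes rose.

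From 10 to 20 days in females, Serpina3n rose by 3.10 ± 0.46 (SE), Prodh, the proline dehydrogenase, by 1.32 ± 0.18, Osmr by 0.99 ± 0.15, Atoh8 by 1.54 ± 0.25 and Tmem100 by 2.14 ± 0.36. Col15a1 lay lower, at -0.84 ± 0.14, Tab1 at -0.51 ± 0.09, Mrtfa at -0.96 ± 0.17, Ecm2 at -0.70 ± 0.13 and Cspg4 at -0.77 ± 0.16. In males Osmr rose by 1.22 ± 0.15, Entpd1 by 0.87 ± 0.11, Csf2rb2 by 2.09 ± 0.30, Serpina3n by 3.14 ± 0.46 and Gpr182 by 1.45 ± 0.23. Col15a1 lay lower, at -0.69 ± 0.14, Foxo6 at -1.32 ± 0.30, Papln at -2.03 ± 0.46, Abi3bp at -0.63 ± 0.15 and Prnd at -3.33 ± 0.78. From 20 to 25 days in males, Arid5a rose by 1.05 ± 0.18, Sbno2 by 1.08 ± 0.19, Ankrd10 by 0.73 ± 0.14 and Impact by 0.69 ± 0.13. Coa7 lay lower, at -0.55 ± 0.09, Pkm at -0.63 ± 0.12, Klhl23 at -0.82 ± 0.16, Smox at -0.72 ± 0.15 and Mettl11b at -0.75 ± 0.15. IL-6, STAT3 and acute phase genes rose from 10 to 20 days in 11 of 24 in females and 14 of 24 in males (14 and 21 adjusted over the list alone, camera adjusted p = 3.2e-13 and 8e-19, adjusted p = 0.022 and 0.0034 with an estimated correlation), and in 4 of 24 from 20 to 25 days in males (12 adjusted over the list alone, camera adjusted p = 7.8e-09, adjusted p = 0.12 with an estimated correlation). By edgeR 207 genes (156 higher) passed from 10 to 20 days in females, 152 (127 higher) in males, and 219 (104 higher) from 20 to 25 days in males. From 20 to 25 days in females 0 passed (1104 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma-voom). Without the libraries rich in Alb the male 20 against 10 days count was 24, with 18 genes higher in all where all libraries gave 127, and the 14 list members were not counted again. It was 67 and 94 without male 20 days replicates 3 and 5. The male 25 against 20 days count ran from 46 to 823 as single libraries were left out and was 0 with the other groups left out, and the female 20 against 10 days count ran from 86 to 433 as single libraries were left out.

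Between the sexes, 48 genes passed in the same direction at 20 days, 46 higher and 2 lower, where chance gives 1.57 and 0.081 (Fisher's exact test, one-sided, 2.9e-56 and 0.0029). They included Retnlg, Serpina3n, S100a9, S100a8, Mt1, Mt2, Cxcr2, C4b, Mmp3 and Papln. At 25 days 434 were shared, 339 higher and 95 lower (chance 48.4 and 17.1, 2.6e-248 and 2.1e-51), led by Saa3, Retnlg, Lcn2, Serpina3n, S100a9, Mt2, Mt1, S100a8, Cxcl13 and Il1f9. Across genes, which are not independent replicates, the log2 changes of the sexes correlated at r = 0.503 (Spearman 0.546) at 25 days and 0.274 (0.436) at 20 days. Of the genes called in males at 25 days 90.1% had the same sign in females. Within a sex, 20 and 25 days shared 154 genes in females and 152 in males. Simulated unchanged groups with shared controls shared 0. Almost no gene was called in them, so that value cannot show how far shared controls raise the overlap. Chance overlap of independent lists was 4.66 higher and 0.859 lower in females and 16.2 and 1.61 in males. With the controls split the shared number had a median of 7.5 and 23.5, and the covariance of log2 changes was 0.156 in females (0.0721 simulated, 0.112 split) and 0.281 in males (0.0644 simulated, 0.237 split). Splitting also lowered the calls at 20 days, to at most 57 genes higher in females and 38 in males, against 176 and 140 with all controls. The shared numbers fall with those calls, so they do not measure the part due to shared controls.

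Few genes passed the test of a difference between the sexes in the response to C26, which had low power. In simulated data it recovered 16.4% of 1.5-fold and 43.3% of 2-fold differences at 25 days. At 25 days Tmem41b (male minus female log2 change 0.60 ± 0.11, SE), Tmem33 (0.54 ± 0.11), Ahsa2 (0.55 ± 0.12), a cochaperone gene, Fam213a (0.62 ± 0.13) and Xist (7.79 ± 1.62, from male replicate 2) were higher in the male response, and Faap100 (-1.08 ± 0.18) and Syt3 (-1.13 ± 0.24) lower. Heat shock genes differed as a set (camera adjusted p = 2.3e-16, adjusted p = 0.0026 with an estimated correlation), with 0 of 18 passing over all genes and 13 adjusted over the list alone. In PBS controls 2 of these 18 were already lower in males (5 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.80 with an estimated correlation). The same PBS libraries enter the test of the response, so a difference between the controls can add to it. Hsp90aa1 had a log2 change of -0.43 ± 0.22 in females and 0.87 ± 0.20 in males, and Hspa1a of -0.59 ± 0.69 and 1.86 ± 0.63. By edgeR 10 genes passed at 25 days (8 higher in the male response), a count that ran from 3 to 133 as single libraries were left out and was 50 by DESeq2, 671 with quality weights and 0 with the other groups left out. At 20 days 0 passed (558 at an unadjusted p under 0.05, DESeq2 11, limma-voom 0), and at 10 days 1, the predicted gene Gm8818 (5.58 ± 1.06, adjusted p = 0.0345), named after its values were seen, which was lost by limma-voom and without the filter.

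**Figure D3:**
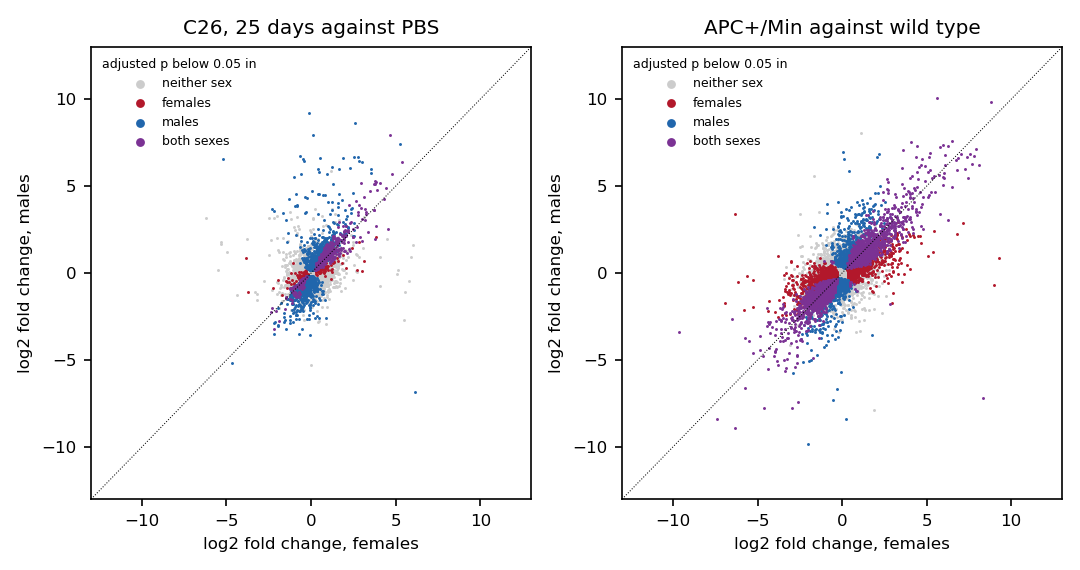
Log2 change in females (horizontal axis) against log2 change in males (vertical axis), each point a gene, for C26 at 25 days and for APC+/Min. At 25 days 434 genes and in APC+/Min 3020 genes were called in both sexes in the same direction.

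PBS controls themselves differed by sex in 425 genes, 274 higher in males and 151 lower. The Y-linked genes Ddx3y, Eif2s3y and Uty were at least 4310-fold, 2150-fold and 613-fold higher in males, and Kdm5d had a ratio of 2170 (389 to 85600) against 1 count in females. The peptide transporter gene Slc15a5 was higher by 6.07 ± 0.49 (SE). Xist was lower in males, at -11.05 ± 1.34, as were the imprinted RNA H19 at -1.49 ± 0.16, Cyfip2 at -2.75 ± 0.35, Rab15 at -2.09 ± 0.30 and Ankrd2 at -3.50 ± 0.58. H19 averaged 528 ± 66.7 CPM (SD) in males and 1482 ± 210 CPM in females. Slow fibre genes were lower in males in 8 of 15 cases (11 adjusted over the list alone, camera adjusted p = 1.1e-09, adjusted p = 0.12 with an estimated correlation). Myoz2 was at -1.58 ± 0.27, Casq2 at -0.96 ± 0.19 and Lmcd1 at -1.23 ± 0.26. Ankrd2 was at 30.3 ± 24.6 CPM (SD) in PBS males against 343 ± 306 CPM in PBS females. These female libraries were also the controls of females at 20 days, where Ankrd2, Casq2 and Lmcd1 were lower too, so these results are not independent. The count was 3409 with quality weights and 2789 with the other groups left out, and 245 and 255 without female replicates 5 and 6 and 279 and 276 without male replicates 4 and 7.

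Muscle of APC+/Min females held far more mRNA of Fbxo32 and Trim63, with 1 library apart. Relative to library totals, replicate 1 held 696 CPM of Fbxo32 and 499 CPM of Trim63 where the other 5 held at least 2940 and 2150 CPM. Fbxo32 rose 6.08-fold to 2565 ± 907 CPM (SD, n = 6) from 422 ± 57.8 CPM (n = 8, adjusted p = 1.9e-06) and Trim63 10.4-fold to 2196 ± 940 from 211 ± 69.7 CPM (adjusted p = 2.8e-06). In the ubiquitin ligase list as a whole 9 of 20 rose and 4 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.061). Lcn2 rose by 7.26 ± 0.88 log2 units (SE), the red cell gene Slc4a1 by 6.77 ± 0.76, Chil3 by 6.08 ± 1.02 and S100a8 by 6.07 ± 0.82. Retnlg had a ratio of 539 (96.3 to 21300) against 1 count in wild types. Myh2, the fast oxidative myosin, lay lower, at -4.39 ± 0.88 (54.8 ± 44.4 against 1149 ± 721 CPM), the muscle secreted peptide gene Ostn at -4.38 ± 0.81, Gfra2 at -4.41 ± 0.87 and Inpp5j at -4.32 ± 0.65, and Gbp10 was at least 229-fold lower. By edgeR 5622 of 14795 genes passed, 2981 higher and 2641 lower.

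Respiratory chain genes fell together in APC+/Min females. Of the nuclear-encoded oxidative phosphorylation genes 41 of 44 fell (42 adjusted over the list alone, camera adjusted p = 8.5e-20, adjusted p = 0.19 with an estimated correlation). Cyc1 was at -1.62 ± 0.20 and Uqcrc1 at -1.36 ± 0.18. Mitochondrially encoded transcripts fell in 12 of 13 (12 adjusted over the list alone, 2.1e-05, adjusted p = 0.39 with an estimated correlation). mt-Nd4l was at -1.13 ± 0.21. Tricarboxylic acid cycle genes fell in 15 of 20 (17 adjusted over the list alone, 3.3e-08, adjusted p = 0.26 with an estimated correlation). Mpc2 was at -1.30 ± 0.16. Fast fibre genes fell in 12 of 18 (12 adjusted over the list alone, 0.00012, adjusted p = 0.39 with an estimated correlation). Glycolysis and glycogen genes fell in 13 of 27 and rose in 3 (15 and 3 adjusted over the list alone, 7.9e-05, adjusted p = 0.37 with an estimated correlation). Pfkm was at -1.59 against Gpi1 at 1.37. Extracellular matrix genes fell in 24 of 34 and rose in 3 (24 and 4 adjusted over the list alone, 1.6e-06, adjusted p = 0.37 with an estimated correlation). Col15a1 was at -1.87 ± 0.28, against Lox, a collagen cross-linking enzyme, at 2.55 ± 0.31, Mmp9 at 1.92 and Mmp14 at 0.66. Fibro-adipogenic progenitor markers fell in 15 of 18 (15 adjusted over the list alone, 3.6e-08, adjusted p = 0.19 with an estimated correlation). Pi16 was at -3.63 ± 0.53. Proteasome genes rose in 28 of 33 (28 adjusted over the list alone, 2.7e-08, adjusted p = 0.40 with an estimated correlation). Psmd8 was at 2.44 ± 0.29. Autophagy and lysosome genes rose in 18 of 29 and fell in 2 (18 and 2 adjusted over the list alone, 5.4e-05, adjusted p = 0.39 with an estimated correlation). Bnip3 was at 2.44 ± 0.28 and Ctsl at 2.37 ± 0.29 against Ulk2 at -1.15 ± 0.31. Glucocorticoid and FoxO genes rose in 19 of 24 (19 adjusted over the list alone, 1.1e-07, adjusted p = 0.26 with an estimated correlation). Eif4ebp1 was at 3.48 ± 0.39. IL-6, STAT3 and acute phase genes rose in 13 of 19 (13 adjusted over the list alone, 9.6e-07, adjusted p = 0.19 with an estimated correlation). Osmr was at 1.68 ± 0.17. The mitochondrial share of counts averaged 10.6 ± 2.68% (SD) in these libraries against 17.9 ± 2.11% in wild types, and their length slope 0.104 ± 0.0783 against -0.0197 ± 0.0877. With the slope as a covariate 35 oxidative phosphorylation genes, 6 mitochondrially encoded transcripts and 6 fast fibre genes fell, and 9 histone modification genes rose and 4 fell.

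Erythroid markers also rose in APC+/Min females, in 8 of 9 (8 adjusted over the list alone, camera adjusted p = 5.5e-07, adjusted p = 0.26 with an estimated correlation). Hba-a1 was at 3.87 ± 0.49. Neutrophil markers rose in 9 of 10 (9 adjusted over the list alone, 1.1e-07, adjusted p = 0.19 with an estimated correlation), while of 16 macrophage markers 1 rose and 1 fell (1 and 1 adjusted over the list alone, 0.40). Ribosomal protein genes rose in 34 of 43 (38 adjusted over the list alone, 2.7e-08, adjusted p = 0.45 with an estimated correlation). Rpl3 was at 1.83 ± 0.33. Histone modification genes rose in 12 of 33 and fell in 3 (12 and 3 adjusted over the list alone, 0.022, adjusted p = 0.26 with an estimated correlation). Crebbp was at 1.34 ± 0.16 and the methyltransferase Kmt2d at 1.32 ± 0.17 against Smyd1 at -1.19. Circadian genes rose in 7 of 19 and fell in 1 (8 and 1 adjusted over the list alone, 0.0086, adjusted p = 0.19 with an estimated correlation). Cry2 was at 3.02 ± 0.48, against Bhlhe41 at -0.71 ± 0.27. DNA methylation genes rose in 5 and fell in 4 of 19 (camera adjusted p = 0.68), with Tet2 at 1.18 ± 0.24 against Dnmt1 at -0.93 ± 0.17 and Dnmt3a at -1.21 ± 0.25, the list's median at 0.22 and its mean at -0.03. Interferon genes fell in 8 of 27 (7 adjusted over the list alone, 0.0035, adjusted p = 0.46 with an estimated correlation). Ifit3b was at -2.98 ± 0.50.

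In APC+/Min males Fbxo32 rose 4.29-fold (1429 ± 878 CPM, SD, n = 6, against 333 ± 101, n = 8, adjusted p = 2.7e-05) and Trim63 rose 6.53-fold (1047 ± 879 against 160 ± 53.3 CPM, adjusted p = 3.7e-05). Replicate 2 stood apart. Relative to library totals it held 252 CPM of Fbxo32 and 140 CPM of Trim63, within the wild type ranges of 205 to 493 and 97.8 to 248 CPM. The other APC+/Min males held at least 1090 and 483 CPM. Of 20 ubiquitin ligase genes 3 rose and 6 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.48), the median at -0.16 and the mean at 0.05. S100a9 rose by 6.91 ± 0.79 log2 units (SE), S100a8 by 6.76 ± 0.81, Apol11b by 6.68 ± 0.94 and Ngp by 6.62 ± 1.17. Foxo6os lay lower, at -5.62 ± 0.82, Ostn at -5.53 ± 0.91 and Fat3 at -5.28 ± 1.08, Kera and Irx3os were at least 125-fold and 251-fold lower, and Chad was lower by a ratio of 380 (67.9 to 15100) with 1 count left. By edgeR 4902 genes passed, 2457 higher and 2445 lower.

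All 43 ribosomal protein genes rose in APC+/Min males (43 adjusted over the list alone, camera adjusted p = 5e-27, adjusted p = 0.23 with an estimated correlation). The length slope averaged -0.0928 ± 0.0637 (SD) in these libraries against 0.0116 ± 0.0963 in wild types. Rps20 was at 2.05 ± 0.27 and Rpl23 at 1.63 ± 0.23. Tricarboxylic acid cycle genes fell in 18 of 20 and rose in 1 (18 and 1 adjusted over the list alone, 2.6e-10, adjusted p = 0.23 with an estimated correlation). Pdhx was at -1.29 ± 0.18, against Idh2 at 0.86 ± 0.26. Fatty acid oxidation genes fell in 17 of 23 and rose in 1 (17 and 1 adjusted over the list alone, 1.6e-06, adjusted p = 0.39 with an estimated correlation). Acads was at -1.62 ± 0.24 against Mlycd at 0.74. Oxidative phosphorylation genes fell in 22 of 44 and 1 rose (25 and 1 adjusted over the list alone, 3.9e-08, adjusted p = 0.42 with an estimated correlation). Ndufs1 was at -2.03 ± 0.28 against Cox6a2 at 0.81 ± 0.19. With the length slope as a covariate 37 of the 44 fell. The mitochondrial share averaged 14 ± 4.48% (SD) in APC+/Min males against 21.8 ± 7.22% in wild types, of which replicates 1 and 2 stood highest, at 31.9% and 33.3% (the others 23.9% or less), with length slopes of -0.127 and -0.137. Proteasome genes rose in 26 of 33 and 1 fell (27 and 1 adjusted over the list alone, 1.6e-07, adjusted p = 0.42 with an estimated correlation). Psma7 was at 1.84 ± 0.31 against Psme4 at -0.71 ± 0.19. Extracellular matrix genes fell in 25 of 34 and rose in 4 (26 and 4 adjusted over the list alone, 1.6e-07, adjusted p = 0.39 with an estimated correlation). Col15a1 was at -1.99 ± 0.28 against Lox at 2.06. Fibro-adipogenic progenitor markers fell in 15 of 18 and rose in 1 (15 and 1 adjusted over the list alone, 3e-07, adjusted p = 0.23 with an estimated correlation). Glucocorticoid and FoxO genes rose in 14 of 24 (15 adjusted over the list alone, 4.9e-07, adjusted p = 0.38 with an estimated correlation). Eif4ebp1 was at 3.82 ± 0.40. IL-6, STAT3 and acute phase genes rose in 12 of 19 and fell in 1 (15 and 1 adjusted over the list alone, 1.1e-06, adjusted p = 0.23 with an estimated correlation). Osmr was at 1.70 ± 0.17 against Lifr at -0.50 ± 0.14. Erythroid markers rose in 8 of 9 (8 adjusted over the list alone, 2.6e-10, adjusted p = 0.23 with an estimated correlation). Neutrophil markers rose in 9 of 10 (9 adjusted over the list alone, 2.2e-10, adjusted p = 0.079 with an estimated correlation). Dnmt3a lay lower, at -1.80 ± 0.26 in a DNA methylation list with 4 higher and 2 lower of 19 (camera adjusted p = 0.83), and Amd1, of polyamine synthesis, lay lower, at -3.75 ± 0.37 in a list with 3 higher and 4 lower of 12 (0.12).

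**Figure D4:**
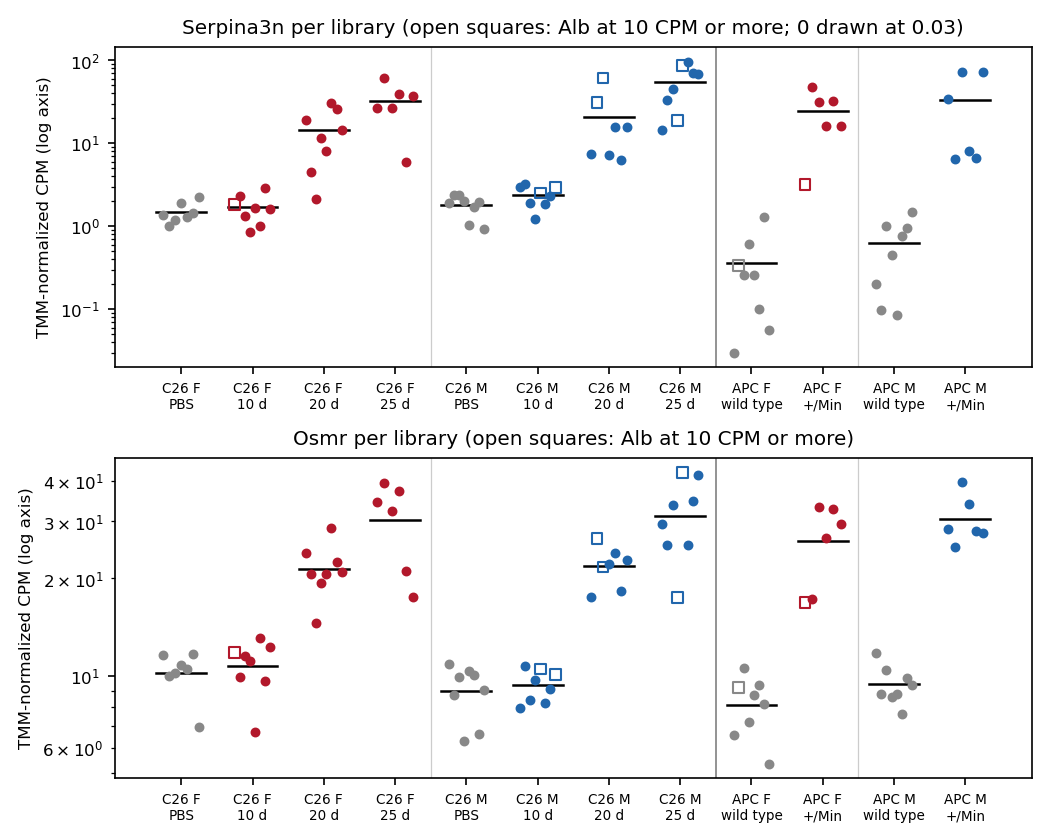
TMM-normalized CPM (log axis) of Serpina3n and Osmr in each library by group, with points for libraries, bars for group means and open squares for libraries with Alb at 10 CPM or more. A Serpina3n level of 0 in APC female wild type replicate 1 is drawn at the foot of the axis, and Serpina3n averaged 20.8 CPM in C26 males at 20 days against 1.81 CPM after PBS.

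The sexes of the APC model shared 3020 calls in the same direction, 1608 higher and 1412 lower, where chance gives 495 and 436, and 15 genes were called in opposite directions. Across genes, which are not independent replicates, r was 0.708 and Spearman's rho 0.685. H19 differed in its response (male minus female 1.75 ± 0.33, SE), at -1.06 ± 0.24 in females and 0.69 ± 0.23 in males, as did Kmt2d (-1.29 ± 0.24), Cdk19 (-1.57 ± 0.28), Wnk2 (-1.36 ± 0.26), Amd1 (-2.41 ± 0.46) and Slc15a5 (-4.59 ± 0.88). Higher in the male response were Gstm2 (1.48 ± 0.30), the copper chaperone Ccs (1.36 ± 0.28), Amy1 (1.21 ± 0.26) and Asl (2.02 ± 0.44). By edgeR 20 genes passed, 5 higher and 15 lower in the male response, a count that ran from 0 to 613 as single libraries were left out and was 260 by DESeq2 and 2066 with quality weights. With the length slope 7 were higher and 3 lower, and 2 of the 20 genes were among them. Histone modification genes lay lower in the male response, with 1 of 33 passing (6 adjusted over the list alone, camera adjusted p = 0.00056, adjusted p = 0.088 with an estimated correlation).

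Wild types of the APC model differed by sex in 129 genes, 104 higher in males and 25 lower. Ddx3y, Eif2s3y and Uty were at least 3640-fold, 2430-fold and 640-fold higher in males, Actr3b was higher by 3.40 ± 0.33 (SE) and Xist was at least 7220-fold lower. H19 was lower at -1.72 ± 0.22, Cyfip2 at -3.60 ± 0.51, Hmgn5 at -1.15 ± 0.17 and Kdm6a at -0.96 ± 0.17. Polyamine genes were higher in males in 3 of 12 (4 adjusted over the list alone, camera adjusted p = 8e-05, adjusted p = 0.010 with an estimated correlation). Amd1 was at 2.46 ± 0.31, Odc1 at 1.44 ± 0.25 and Smox at 1.60 ± 0.33. The count was 273 by DESeq2, 1495 with quality weights and 572 with the other groups left out, and 78, 82 and 84 without female replicates 2, 4 and 7.

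C26 at 25 days and APC+/Min shared 313 genes in females, 224 higher and 89 lower, where chance gives 80.7 and 28.2 (Fisher's exact test, one-sided, 1.1e-57 and 6.8e-28), and 19 genes were called in opposite directions. Retnlg, Lcn2, Serpina3n, Mt2, S100a8, Mt1, Mmp8, S100a9, Gp1bb and Cxcl13 had the largest joint changes. In males 1868 genes were shared, 921 higher and 947 lower (chance 285 and 276), with Retnlg, S100a9, Wfdc21, S100a8, Lcn2, Serpina3m, Mt2, Mt1, Serpina3n and Kera in front, and 50 went in opposite directions. Hspa1a changed by 1.86 in C26 males and -1.87 in APC+/Min males, and Ucp3, a mitochondrial carrier, by 0.62 and -1.88. Across genes, which are not independent replicates, r was 0.392 (Spearman 0.346) in females and 0.562 (0.583) in males. The Fisher tests also treat genes as independent. The length slope was lower than in controls in males of both models, but higher in APC+/Min females. In males a shared length trend of the libraries therefore cannot be told apart from a shared response, and its part in the overlap was not tested.

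**Figure D5:**
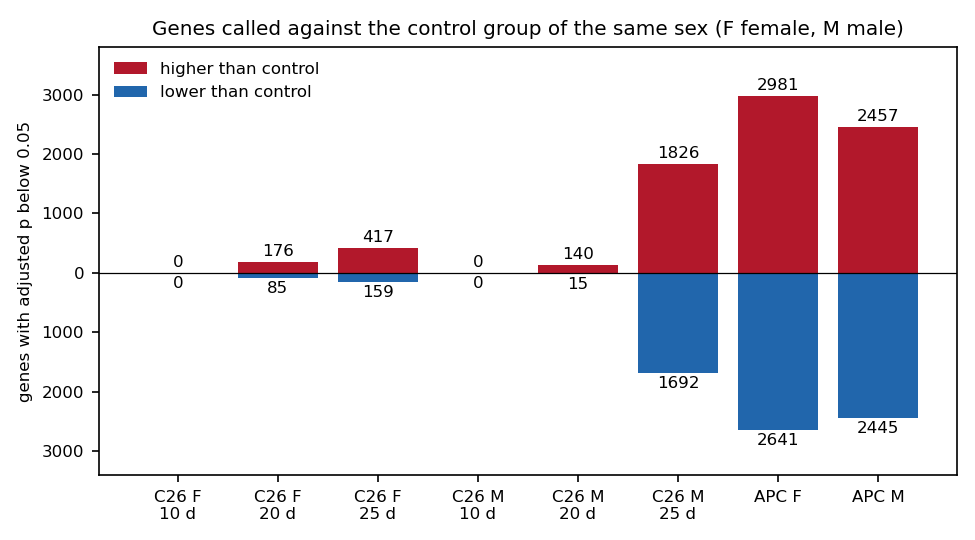
Number of genes called higher and lower in each comparison with PBS or wild type at an edgeR adjusted p below 0.05, as bars from 0. Counts were 0 at 10 days in both sexes, 576 in females and 3518 in males at 25 days, and 5622 in females and 4902 in males of the APC model.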

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

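The alternatives that left out single libraries or those rich in Alb, or added the length slope, and the test of female 25 days replicate 6 as the cause of the lower female count were chosen after the data were seen, as was the rule that weighs the macrophage and lymphocyte markers of APC+/Min males against their spread.

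Within groups of libraries, 17 of 141 tests of the most extreme library found it far from the rest. Chance gives about 1 in 20 for independent tests of normally distributed values. Some measures were raw CPM near 0, such as Alb, and the measures of a library are related, so the excess over chance is not measured. Female 25 days replicate 6 stood apart in length slope (-0.524, next 0.014), ribosomal protein level (mean log2 CPM 8.99, next 7.09), macrophage marker level (5.3, next 3.47), mitochondrial share (10.5%, next 15.4%) and Xist (48.4 CPM, next 260). Male 20 days replicate 2 stood apart in length slope (-0.291, next 0.018), ribosomal protein level (7.89, next 6.98) and Ddx3y (44.5 CPM, next 79.6). Alb was high in female 10 days replicate 1 (19.3 CPM, next 6.34), female 20 days replicate 3 (3.16, next 1.34), male PBS replicate 7 (7.85, next 2.13) and male 20 days replicate 3 (189, next 16.9). Xist was at 191 CPM in male 25 days replicate 2 (next 0.293) and Trim63 at 987 CPM in male 25 days replicate 6 (next 394). In the APC experiment, wild type female replicate 6 had a mitochondrial share of 22.7% (next 18.6%), wild type female replicate 1 a neutrophil marker level of -3.29 (mean log2 CPM, next -2.86) and APC+/Min female replicate 1 an IL-6, STAT3 and acute phase level of 3.08 (next 4.31).

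A test of the difference between the sexes in the response found 1 gene at 10 days, 10 genes at 25 days and 20 genes in the APC model. The differences, male minus female on the log2 scale, were 0.60 for Tmem41b, 0.54 for Tmem33, 0.55 for Ahsa2, 7.79 for Xist, 0.62 for Fam213a, -1.08 for Faap100 and -1.13 for Syt3 at 25 days. In the APC model they were 1.75 for H19, 1.48 for Gstm2, 1.36 for Ccs, 1.21 for Amy1, 2.02 for Asl, -1.57 for Cdk19, -1.29 for Kmt2d, -1.36 for Wnk2, -2.41 for Amd1 and -4.59 for Slc15a5.

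Liver-type acute phase genes were higher in C26 males, and a candidate source is liver RNA in libraries with Alb at up to 189 CPM. Without the 7 libraries with Alb at 10 CPM or more, the median log2 change of 9 such genes at 20 days went from 6.38 (median SE 1.4) to 1.12 (1.01) and 0 of them passed, as that source predicts. Orm1, Itih3 and Itih4 among them stood outside the fixed list and had high fold changes in these same males. The starting median is therefore raised by that choice and does not measure the response of the set. The median of the other IL-6, STAT3 and acute phase genes went from 0.95 to 0.73 at 20 days, with 4 of 6 calls left. With 76.7% of the change kept, this lay only just above the bound set before. At 25 days it went from 1.83 to 1.92, with 16 calls before and after. These values argue against liver RNA as their whole cause, narrowly so at 20 days. At 25 days the liver-type genes went from 6.01 to 2.90 and 6 of 9 passed, so liver RNA and a response of muscle cannot be told apart there, since the libraries left out are also tumour libraries. A response to the tumour in muscle itself stays open and was not tested apart.

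More genes were called in C26 males than in females at 25 days. In 20 draws of 6 tumour and 7 PBS libraries from the males, as many as the females had, the lowest male count was 1837 against 576 in females, which argues against group size as the cause. Leaving out female 25 days replicate 6 lowered the female count to 421, which argues against a spread widened by that library as the whole cause. A part may come from it, since quality weights gave 1555 genes in females (4471 in males), and the count for the sex difference went from 10 to 133 without it and to 671 with quality weights. A difference between the sexes stays open as well.

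Ribosomal protein genes were higher in C26 males at 25 days and in APC+/Min males, and a length trend of the libraries is a candidate cause. With the slope as a covariate the median log2 change in C26 males went from 0.65 (interquartile range 0.2) to 0.16 (0.097) and the calls from 30 to 19, as a length trend predicts. With 24.8% of the change kept, this lay only just below the bound set before. The slope also differs between these tumour libraries and PBS, so a length trend and a tumour effect that follows the slope cannot be told apart. In APC+/Min males the median was 0.96 with the slope and all 43 genes passed, with 74% of the change kept, and the trend cannot be told apart from an effect of genotype because the slope differs between the genotypes, although in APC+/Min females these genes rose in 34 of 43 while the slope was higher (0.104 ± 0.0783, SD) than in wild types (-0.0197 ± 0.0877). RNA of macrophages or lymphocytes would raise their markers too, and their median was 0.71 (interquartile range 1.1) over 22 genes in C26 males, although 7 passed, Lyz2 (160 ± 171 against 67.9 CPM) did not and Ighm fell by 1.92. In APC+/Min males the marker median was 0.90 with an interquartile range of 1.0. In both models the spread of the markers is too wide to decide, and an effect of the tumour on muscle stays open, untested.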

How the results depend on the processing

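Leaving out single libraries or those rich in Alb, and the length slope, were chosen after seeing the data. No named gene that passed turned its direction under the alternatives other than leaving out single libraries, and no called list under an estimated correlation, DESeq2 size factors or fry. This is weak evidence of stability, since the genes were named for their fold or p in these same data. An estimated correlation cannot turn a list, as it alters only the variance of the test. Lists were not tested again with single libraries left out, but without replicate 6 the median of the ribosomal protein genes in C26 females at 25 days was -0.02 against 0.59 with it. The balance of calls did turn, from 5 higher and 15 lower to 7 and 3 with the length slope for the sex difference in the APC response (2 genes shared), from 8 and 2 to 311 and 360 with quality weights for that at 25 days, from 1826 and 1692 to 1636 and 2011 by limma-voom and 2220 and 2251 with quality weights in males at 25 days, from 104 and 115 to 117 and 109 with the stricter filter and 43 and 38 without the filter from 20 to 25 days in males, from 274 and 151 to 1693 and 1716 with quality weights after PBS, from 2981 and 2641 to 2922 and 2946 by limma-voom in APC females, and from 2457 and 2445 to 2376 and 2934 by limma-voom and 2441 and 2851 with quality weights in APC males. Of 671 results for named genes, 3 lost their call with DESeq2 size factors, 34 with the length slope, 41 with quality weights, 49 without the filter, 49 with the replicate number as a block and 67 by limma-voom. Of those that could be compared, 1 of 667 lost it by DESeq2, 0 of 669 with the stricter filter, 67 of 648 with only the groups compared and 29 of 349 without the Alb-rich libraries. Counts of genes that moved by over 1.5 times follow, and the cause was not tested. By DESeq2 they were 5 (main 0) and 405 (261) in C26 females at 10 and 20 days, 2 (0) in males at 10 days, 364 (207) and 3 (0) from 10 to 20 and 20 to 25 days in females, 242 (152) and 433 (219) in males, 3 (1), 11 (0) and 50 (10) for the sex difference at 10, 20 and 25 days, 260 (20) for that in the APC response and 273 (129) for wild types by sex. By limma-voom they were 70 (155) in males at 20 days, 333 from 20 to 25 days in males and 0 for the sex difference at 10 days. With quality weights they were 1555 (576) in females at 25 days, 327 in males at 20 days, 404 and 1043 for the male time steps, 0 and 671 for the sex difference at 10 and 25 days, 3409 (425) after PBS, 2066 in the APC response and 1495 in wild types. Without the filter they were 151 and 376 in females at 20 and 25 days, 26 (0) in males at 10 days, 109 from 10 to 20 days in females, 81 from 20 to 25 days in males, 0 and 2 for the sex difference at 10 and 25 days and 7 in the APC response. The stricter filter gave 0 and 1 for the sex difference at 10 and 20 days. With the length slope they were 474 and 925 in females at 20 and 25 days, 572 and 8 for the female time steps, 235 and 771 for the male ones, 1 and 91 for the sex difference at 20 and 25 days, 10 in the APC response and 326 in wild types. Without the Alb-rich libraries they were 42 in males at 20 days, 24 and 752 for the male time steps, 34 for the sex difference at 25 days and 652 after PBS. With only the groups compared they were 134 in females at 20 days, 105 from 10 to 20 days in females, 0 from 20 to 25 days in males, 0 and 0 for the sex difference at 10 and 25 days, 2789 after PBS and 572 in wild types. Lists called by camera numbered 0, 3, 3, 0, 3, 2, 0 and 0 with an estimated correlation (C26 females at 10, 20 and 25 days, males likewise, APC females and males) where the preset one gave 14, 19, 19, 5, 15, 20, 22 and 21, and by fry 0, 7, 5, 0, 3, 23, 28 and 28. Of 48 genes shared by the sexes at 20 days, 12 were left at an adjusted p below 0.01, and 20 and 25 days shared 7.5 (females) and 23.5 (males) with split controls and 0 in simulated unchanged groups. Fewer genes were called at 20 days with split controls, and almost none in the simulated groups. These values therefore do not measure the effect of shared controls on the overlap. As a replicate block, the number gave 98 genes in males at 20 days, 98 from 10 to 20 days in males, 5 for the sex difference at 25 days, 273 after PBS, 0 in the APC response and 72 in wild types, turned the balance in APC males to 1903 higher and 1974 lower, and moved no other count of genes by over 1.5 times. Numbers did not pair the libraries, since deviations of same-numbered ones correlated at -0.019 on average in C26 (3 of 60 closest to their own number) and -0.0164 in APC (6 of 28).

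Leaving out single libraries gave 121 to 368 genes in C26 females at 20 days, 401 to 741 at 25 days, 71 to 203 and 2651 to 4217 in males at 20 and 25 days, 4594 to 6570 in APC females, 4155 to 5253 in APC males, 245 to 547 after PBS and 78 to 154 in wild types. From 10 to 20 days in females it gave 86 to 433 (108 without 10 days replicate 3, 105, 433, 318, 116 and 86 without 20 days replicates 1, 3, 5, 6 and 7), and from 20 to 25 days 0 to 3 (1 and 3 without 25 days replicates 5 and 6). In males it gave 67 to 200 from 10 to 20 days and 46 to 823 from 20 to 25 days (64, 470, 87 and 50 without 20 days replicates 1, 2, 4 and 6, and 591, 140, 77, 823, 126, 46, 64 and 67 without 25 days replicates 1 to 8). For the sex difference it gave 0 to 2 at 10 days, 0 to 4 at 20 days and 3 to 133 at 25 days (133 without female 25 days replicate 6, 39, 19 and 16 without male 25 days replicates 4, 1 and 6, and 3 to 6 without female PBS replicates 2, 5 and 6, female 25 days replicates 1 to 5, male PBS replicates 3, 4, 7 and 8, or male 25 days replicate 3). For the sex difference in the APC response it gave 0 to 613 (613 without male APC+/Min replicate 1, 513 without female APC+/Min replicate 1, 271 without male wild type replicate 2, and 0 without female APC+/Min replicate 4, male wild type replicates 4, 6, 7 and 8 or male APC+/Min replicate 5), and each library but female wild type replicate 7 and female APC+/Min replicate 3 moved it by over 1.5 times, so that this count rests on single libraries. In simulated data 74.6% of genes changed 2-fold were recovered in females at 25 days, 79.1% in males, 43.3% for the sex difference at 25 days, 44.8% in APC females and 22.4% for the sex difference in APC, which limits the smaller counts.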

Other observations

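Of the tests in this part, leaving out single libraries and the libraries rich in Alb was chosen after the data were seen. Polyamine genes differed between the sexes without a tumour. In PBS males Amd1, the decarboxylase that supplies spermidine synthesis, was higher by 1.59 ± 0.18 (SE, log2) and Smox, which oxidizes spermine, by 0.98 ± 0.15, with 3 of 13 genes passing (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.28 with an estimated correlation). The circadian genes Bhlhe41, Hlf and Tef were also higher in PBS males, by 1.09, 0.91 and 0.42 (3 of 19, with 6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00011, adjusted p = 0.15 with an estimated correlation).

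Integrated stress genes rose in APC+/Min females in 13 of 25 and fell in 2 (14 and 2 adjusted over the list alone, camera adjusted p = 0.00034, adjusted p = 0.26 with an estimated correlation). In males 10 of 25 rose (11 rose and 3 fell adjusted over the list alone, 0.015, adjusted p = 0.42 with an estimated correlation). Ppp1r15a, a phosphatase subunit that restores translation after stress, was at 2.36 and 2.42. Among 23 denervation genes 6 rose and 4 fell in females (camera adjusted p = 0.93) and 8 rose and 3 fell in males (0.31). Runx1 was at 3.27 and 3.22. Of 19 myogenic genes 2 rose and 7 fell in females (0.080) and 7 rose and 4 fell in males (0.66), with Myod1 at -1.98 in females and the embryonic myosin Myh3 at 3.97 ± 0.88 in males.

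Each count of genes was set against 40 splits of the same libraries into groups of the same sizes, the real split included. For a sex difference in the response, the splits shuffled the sexes among the tumour or APC+/Min libraries and among the controls. Such groups mix sexes that differ without a tumour, so these splits are not a true null for that test and cannot decide on chance. The real split alone, 1 of 40, was as large for 261 genes in C26 females at 20 days (highest other split 40), 576 at 25 days (198) and 3518 in C26 males at 25 days (459). The same held for 207 from 10 to 20 days in females (13), the sexes after PBS with 425 (15) and wild types by sex with 129 (0). It also held for APC+/Min females with 5622 (713) and APC+/Min males with 4902 (1090). Chance is an unlikely source of these counts but is not excluded, since 1 of 40 is the lowest share possible and was not corrected over the comparisons. Splits also cannot separate the named groups from library traits that follow them, such as the length trend. For other counts 1 of 40 splits was as large too, but leaving out 1 library brought the count below or level with the highest other split, so chance is left open for them. These were 155 in C26 males at 20 days (highest other 91, 71 without a library, 42 without the libraries rich in Alb), 152 from 10 to 20 days in males (81, 67 without a library), 219 from 20 to 25 days in males (64, 46 without a library), and the sex difference in the response at 10 days with 1 (0, 0 without any of 19 of the 31 libraries) and at 25 days with 10 (7, 3 without a library). Chance is also left open for the 20 genes of the sex difference in the APC response, where 3 of 40 splits were as large and the highest other gave 402. A count of 0 was met by all 40 splits at 10 days in females (highest other 5) and males (0), for the sex difference at 20 days (1) and from 20 to 25 days in females (773). The split that gave 773 genes, many more than the real count, points to a structure of the samples, which was not identified. The split that gave 402 genes mixed the sexes, which differ without a tumour, so it does not show such a structure by itself.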
